A study of Homo sapiens with 18 samples.

How the data were processed

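RNA was measured by sequencing in 18 libraries of the human lung cancer line PC9, in 6 groups of 3. Per the labels, cells grew in RPMI-1640 with 10% serum, RNA was treated with DNase, the ERCC spike-in RNA was added by cell number and libraries were polyA-selected. The submitters' processing notes name Salmon, without a version, as the tool that gave the estimated reads. The deposited tables hold these expected counts, not scaled between libraries, in tables the authors give per gene, repeat name, repeat family, repeat class and ERCC transcript. The genome build, the annotations of genes and repeats and the alignment settings are not given in the sources used here. Each of the 5 tables holds 3 further columns of values that match no sample and were not used here. The groups were taken from the sample titles.

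Gene identifiers were matched to symbols, found for 27814 of 30727 identifiers; those without took 0.246% of gene reads. The repeat name table holds 17319 names, of which 1759 had reads, and is called here the table of subfamilies. Expected counts were rounded and genes kept by the expression filter of edgeR, which left 17594 genes and 1101 subfamilies; 57 repeat families were tested without that filter. Levels are CPM of gene reads, with library sizes multiplied by TMM factors. Library sizes and TMM factors from genes served genes and repeats alike. The quasi-likelihood F-test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) was run in a single fit of the 18 libraries with a term per group, 12 residual degrees of freedom and a biological coefficient of variation of 0.136 for genes. There were 7 contrasts, 6 of them pairwise and 1 the difference between both TSA effects. P-values were adjusted by Benjamini and Hochberg within each contrast, with a threshold of 0.05. Gene reads ran from 32139343 to 128293531 per library. The filters, tests, contrasts, lists and alternatives were fixed before the data were examined.

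A total of 30 gene lists (544 genes, 540 found in the table, 492 tested; HLA-B, HLA-E and HLA-DRA were among those not found) and 14 lists of repeat subfamilies were tested by camera with a preset correlation of 0.01, and again with an estimated correlation and by fry. Members are also counted with adjustment over the list alone. The share of spike-in reads was compared by 2-sided exact permutation tests of the mean log2 ratio to gene reads. Genes were named by a rule: in each pairwise comparison the 10 higher and 10 lower genes with the largest change among those with an adjusted p under 0.05, at least 10 CPM in the higher group and no overlap between the groups, which chance gives for 10% of genes with 3 libraries against 3. Uncharacterised names were skipped, and up to 4 members with the smallest p were named per list; some genes that the rule names are not reported here. EGFR, SETDB1, CDKN1A, MKI67, ALDH1A1, L1HS, L1PA2, L1PA3 and L1PA4 were named always, with 5 subfamilies per direction of at least 1 CPM; for the difference in TSA effects 5 genes and 3 subfamilies per direction were taken by p. Where a group had no reads the fold is a bound against a floor of 3 reads over the group, and with 1 to 3 reads a ratio with an exact counting interval is given; intervals and floors cover counting error only.

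The alternatives were DESeq2 1.42.0 and its size factors, no filter or a filter of 1 CPM in 3 libraries, the replicate letter as a block, the groups compared alone, spike-ins as library sizes, repeat reads as library sizes for repeats, and each library left out in turn. Scaling to spike-ins without DTP_TSA a, and all results without replicate a of both TSA groups, were added after seeing the data. The test was checked on simulated data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.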

Results

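RNA was sequenced from PC9, a human lung cancer line whose growth depends on the kinase EGFR, in 18 libraries that form 6 groups of 3. The groups are untreated cells given the solvent DMSO (parental_DMSO), drug-tolerant persister cells left after 8 days in 1 µM of the EGFR inhibitor erlotinib (DTP), cells after 24 hours in 1 µM erlotinib (erlotinib_24h), cells after 72 hours in 50 µM of the DNA-crosslinking drug carboplatin (carboplatin_72h), and parental and DTP cells given 50 nM of the histone deacetylase inhibitor trichostatin A for 5 hours (parental_TSA and DTP_TSA). The series asks how RNA levels, those of the retrotransposon LINE-1 (L1) among them, differ between parental, drug-treated and drug-tolerant populations. Reads counted to genes numbered 80933355, 83466419 and 79287734 in parental_DMSO, 84650552, 81891900 and 76101016 in DTP, 84125692, 92609922 and 79986544 in erlotinib_24h, 81508180, 74384032 and 71800215 in carboplatin_72h, 68775700, 109368739 and 128293531 in parental_TSA and 32139343, 82570291 and 81744374 in DTP_TSA. The treatment text of the DTP samples also mentions cells sorted by ALDH activity, which no sample title names, and DTP is read here as unsorted cells. Libraries are named here by group and replicate letter. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples.

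The 6 groups separated by their gene levels, with 1 library far from its group. DTP_TSA a gave 46.0% of its reads to the added ERCC spike-in RNA and 7.09% to ribosomal RNA repeats, against at most 0.763% and 3.36% in the other libraries. Its highest Pearson correlation across genes with a library of its own group was 0.938, where the other pair of that group reached 0.995 (genes are not independent replicates). Parental_TSA a also stood somewhat apart, at 0.979 and 0.985, and 4.69% of its gene reads came from mitochondrial genes, against 3.39% and 3.05% in its mates.

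**Figure D1:**
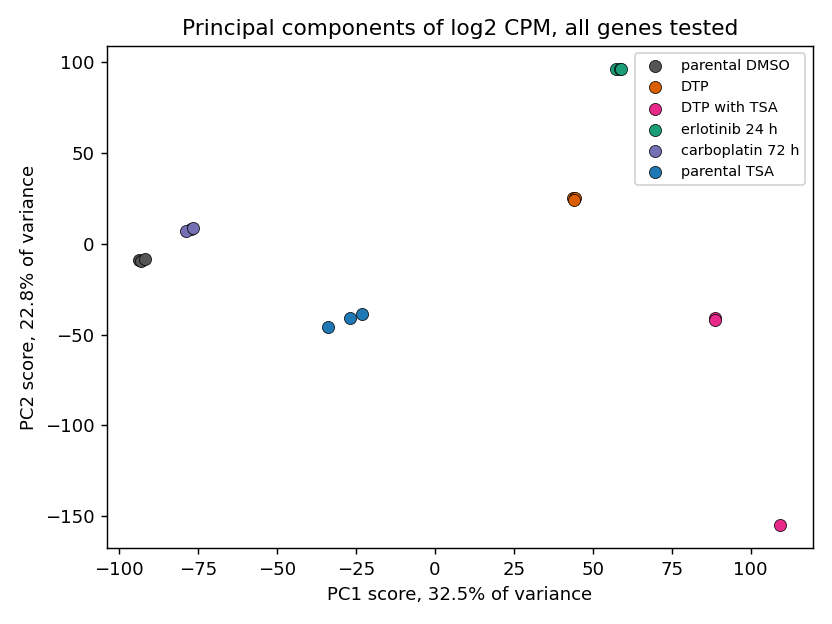
First and second principal components of the log2 CPM values of all tested genes, 1 point per library, coloured by group, with the share of variance on each axis (32.5% and 22.8%). DTP_TSA a lies at 109 and -155, far from the other 2 libraries of its group.

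The spike-in RNA was added by cell number, so its share of reads tracks the amount of messenger RNA per cell inversely. It came to 0.534 ± 0.00805 spike-in reads per 100 gene reads in parental_DMSO (mean ± SD, n = 3), 0.549 ± 0.0177 in DTP, 0.733 ± 0.0311 in erlotinib_24h, 0.380 ± 0.0515 in carboplatin_72h and 0.607 ± 0.155 in parental_TSA, and ran from 0.551 to 99.9 in DTP_TSA. In log2 terms the share differed from parental_DMSO by 0.04 (exact p = 0.3) in DTP, 0.46 (exact p = 0.1) in erlotinib_24h, -0.50 (exact p = 0.1) in carboplatin_72h and 0.16 (exact p = 0.9) in parental_TSA, by 2-sided exact permutation tests whose smallest possible p is 0.1. DTP_TSA differed from DTP by 2.53 (exact p = 0.3), or 0.04 without DTP_TSA a, and DTP from erlotinib_24h by -0.42 (exact p = 0.1). The parental_TSA value turned to -0.04 without parental_TSA a. Changes given from here on are log2 fold changes ± standard error from the edgeR model with 3 libraries per group, scaled to gene reads unless said otherwise. Spike-in scaling stands for scaling to the spike-ins without DTP_TSA a, repeat scaling for scaling repeats to repeat reads, and values without both TSA a leave out replicate a of parental_TSA and of DTP_TSA; spike-in scaling and the values without both TSA a were chosen after seeing the data. For each gene list the count of members that passed is given with the median change and the adjusted p of camera. The count adjusted over the list alone was the same unless given, and calls held with an estimated correlation unless its adjusted p is given. In spike-in scaling the median change of all genes moved from 0.11 to -0.23 after 24 hours of erlotinib, from 0.06 to 0.73 after carboplatin, from -0.08 to 0.11 for TSA in DTP, from 0.03 to 0.48 for DTP against 24 hours, and from -0.11 to 0.05 for the difference in TSA effects.

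DTP cells were compared with parental cells to see what marks the population that survives erlotinib. Interferon-induced genes rose most. Interferon response genes had 25 of 25 members higher (median 5.41, adjusted p = 7.55e-86). IFI6 (10.83±0.19) and BST2 (10.80±0.19), an antiviral tether at the cell surface, and the double-stranded RNA sensors OAS1 (7.45±0.10) and OAS3 (5.35±0.11) were among them. The antigen presentation list rose with them, with 12 of 14 members higher (13 higher adjusted over the list alone, median 2.11, adjusted p = 1.05e-10), including PSMB9 (4.07±0.15), TAP1 (2.26±0.09) and TAPBP (1.96±0.07), which serve peptide loading; HLA-F (4.18±0.16) shares reads with other HLA genes. Mesenchymal markers also rose, with 8 of 14 members higher and 1 lower (median 1.33, adjusted p = 1.12e-05), led by the matrix proteins FN1 (6.00±0.20) and SPARC (5.89±0.57) and by TAGLN (5.54±0.10). Markers of fibroblasts, a cell type that also makes these genes, summed to 65.4 ± 2.37 CPM in DTP and 19.2 ± 0.126 in parental_DMSO.

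Genes of the cell cycle and of EGFR signalling fell in DTP. Mitosis genes had 25 of 25 members lower (median -1.15, adjusted p = 8.79e-14), with CDK1 (-1.25±0.06), PLK1 (-1.25±0.06) and AURKA (-1.15±0.05) among them. DNA replication genes had 23 of 25 members lower (median -0.85, adjusted p = 1.48e-08), with RRM2 (-1.33±0.05) and MCM7 (-0.98±0.04). The EGFR-ERK output list had 3 of 22 members higher and 17 lower (median -1.37, adjusted p = 2.71e-15), and the feedback regulators DUSP6 (-3.49±0.08) and SPRY1 (-3.13±0.12) and the ligand HBEGF (-1.92±0.07) fell strongly. Glycolysis and hypoxia genes went the same way, with 1 of 16 members higher and 14 lower (median -0.66, adjusted p = 4.92e-07), including HK2 (-1.79±0.08) and VEGFA (-1.72±0.07). Lysosome and autophagy genes rose, with 17 of 19 members higher and 1 lower (median 0.75, adjusted p = 1.21e-07), including GABARAPL1 (3.09±0.06) and WIPI1 (2.62±0.07). The proliferation marker MKI67 changed by -1.10±0.18, adjusted p = 5.42e-05, the cyclin kinase inhibitor CDKN1A by -0.70±0.09, adjusted p = 3.53e-06 and EGFR by -0.91±0.32, adjusted p = 0.0232. The histone methyltransferase SETDB1 stood at -0.02±0.10, adjusted p = 0.894, and the aldehyde dehydrogenase ALDH1A1 at -1.62±1.07, adjusted p = 0.209. Cholesterol synthesis genes had 12 of 18 members higher and 3 lower (13 higher and 3 lower adjusted over the list alone, median 0.34, adjusted p = 0.0149, but adjusted p = 0.117 with an estimated correlation). Histone genes expressed outside S phase had 7 of 14 members higher and 4 lower (median 1.06, adjusted p = 0.0302, but adjusted p = 0.370 with an estimated correlation). Ribosomal protein genes had 34 of 38 members lower (median -0.57, adjusted p = 3.23e-04, but adjusted p = 0.543 with an estimated correlation). EGFR lost its call without DTP a, DTP c, parental_DMSO b or parental_DMSO c (-0.90 to -0.88, adjusted p = 0.0538 to 0.0638).

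The 10 largest increases were again mostly interferon-induced. XAF1 had no reads in parental_DMSO and was at least 3764-fold higher in DTP. With 1 to 3 reads in parental_DMSO, read ratios were 14788 (counting interval 5060 to 71708) for OAS2, 12129 (counting interval 2177 to 479078) for IFI44L and 4199 (counting interval 754 to 165861) for TRIM22. IFI44 (10.37±0.22), IFI27 (10.27±0.35) and IGFBP5 (10.23±0.17) followed, as did IFITM1 (10.48±0.34), which shares reads with other IFITM genes. The largest decreases were NTSR1 (-6.59±0.18), IL1RL1 (-5.91±0.27), CCAT1 (-5.25±0.28), IL13RA2 (-5.01±0.42), CEACAM5 (-4.74±0.17), COL6A3 (-4.44±0.33), IL1B (-4.21±0.12), SPRY4 (-3.91±0.20) and COL13A1 (-3.89±0.10) and KRT6B (-4.49±0.32), which shares reads with its paralogs. Of 17594 genes tested, 5465 were higher and 4912 lower at an adjusted p under 0.05 (13250 changed without both TSA a, and 5624 higher and 3219 lower in spike-in scaling), and 11 of 30 gene lists passed (12 without both TSA a).

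Among repeats, the L1 family did not pass in DTP, 0.04±0.04 (adjusted p = 0.611; 0.04 without both TSA a). L1PA2, a young L1 subfamily, rose by 0.88±0.15, adjusted p = 9.41e-04, from 77.2 ± 3.32 to 142 ± 2.47 CPM of gene reads. The human-specific L1HS stood at 0.46±0.15, adjusted p = 0.0591 (73.8 to 78.1 CPM in DTP, 54.5 to 58.0 in parental_DMSO). L1PA3 stood at 0.27±0.13, adjusted p = 0.205 and L1PA4 at 0.35±0.13, adjusted p = 0.0955. The list of youngest L1 subfamilies had 2 of 9 members higher (5 higher adjusted over the list alone, median 0.31, adjusted p = 0.0228, but adjusted p = 0.527 with an estimated correlation). AluY subfamilies had 5 of 20 members lower (median -0.27, adjusted p = 0.00443, but adjusted p = 0.226 with an estimated correlation). AluS had 7 of 17 members lower (1 higher and 10 lower adjusted over the list alone, median -0.21, adjusted p = 0.00400, but adjusted p = 0.527 with an estimated correlation). At the family level centr (1.09±0.25) and ERVK (0.15±0.05) rose and Alu (-0.21±0.05) and L2 (-0.11±0.04) fell. Subfamilies with the largest increases were (GCCCCA)n (4.07±0.49), LTR108a_Mam (3.92±0.54), LTR1C1 (3.79±0.32), HERV15-int (2.68±0.65) and LTR45 (2.29±0.63), and with the largest decreases LTR10B (-4.63±0.50), LTR43B (-3.13±0.46), (CTCTGT)n (-2.40±0.51), MER65-int (-2.01±0.47) and (CAC)n (-1.96±0.43). Of 1101 subfamilies 85 were higher and 67 lower (93 and 35 in spike-in scaling). Without DTP b 99 changed, and without both TSA a, which enter these standard errors, 410. Reads of near-identical subfamilies are shared, and repeat counts do not tell stand-alone repeat RNA from repeats inside other transcripts. ERVK lost its call without any 1 library (0.13 to 0.17, adjusted p = 0.0547 to 0.160). So did L2 (-0.13 to -0.10, adjusted p = 0.0694 to 0.165) and LTR45 (2.23 to 2.42, adjusted p = 0.0508 to 0.0846). Alu (-0.19, adjusted p = 0.0566) and HERV15-int (2.51, adjusted p = 0.0583) lost theirs without parental_DMSO a. MER65-int lost its call without DTP b (-1.79, adjusted p = 0.0519).

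**Figure D2:**
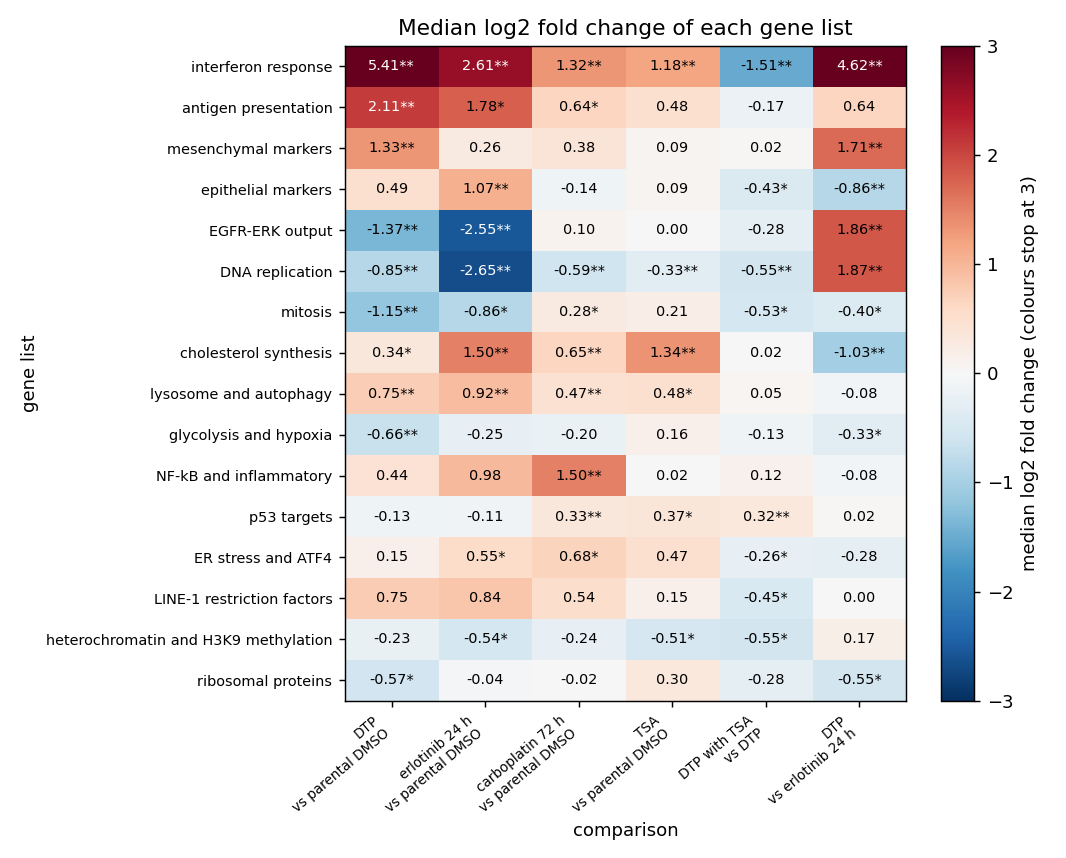
Median log2 fold change of 16 gene lists (vertical axis) in the 6 pairwise comparisons (horizontal axis), with the colour scale ending at 3; 1 asterisk marks a list that passed camera at its preset correlation and 2 mark one that also passed with an estimated correlation. The interferon response median is 5.41 in DTP against parental cells and -1.51 for TSA in DTP, and in spike-in scaling the medians of DNA replication after carboplatin (0.06) and of mitosis (0.05) and glycolysis and hypoxia (0.13) in DTP against 24 hours change sign.

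Cells after 24 hours of erlotinib were compared with parental cells to see the early response to the drug. Proliferation and EGFR signalling genes were far lower. The EGFR-ERK output list had 21 of 22 members lower (median -2.55, adjusted p = 5.83e-24), with ETV5 (-6.15±0.15), DUSP6 (-6.07±0.09) and HBEGF (-5.10±0.08). DNA replication genes had 25 of 25 members lower (median -2.65, adjusted p = 1.59e-36), with CDC6 (-4.20±0.07) and RRM2 (-4.08±0.06). Mitosis genes had 2 of 25 members higher and 21 lower (median -0.86, adjusted p = 1.39e-04, but adjusted p = 0.0964 with an estimated correlation), with CDK1 (-1.97±0.06) and CCNA2 (-1.55±0.05). MKI67 changed by -0.86±0.18, adjusted p = 4.19e-04, EGFR by -1.20±0.32, adjusted p = 0.00340, CDKN1A by -3.47±0.10, adjusted p = 1.13e-14 and SETDB1 by 0.43±0.10, adjusted p = 0.00128. The heterochromatin list had 4 of 22 members higher and 14 lower (median -0.54, adjusted p = 0.0384, but adjusted p = 0.418 with an estimated correlation); the chromatin remodeller HELLS (-2.65±0.09) and the H3K9 methyltransferase SUV39H2 (-2.06±0.07) fell.

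Cholesterol, interferon and epithelial lists rose. Cholesterol synthesis genes had 18 of 18 members higher (median 1.5, adjusted p = 5.08e-14), including INSIG1 (3.58±0.05) and HMGCS1 (2.33±0.08). Interferon response genes had 20 of 25 members higher and 2 lower (median 2.61 or 2.10 with low counts at bound, adjusted p = 1.93e-05), including IFI6 (5.03±0.23), BST2 (4.81±0.23) and IFIT2 (3.86±0.13). Antigen presentation genes had 13 of 14 members higher and 1 lower (median 1.78, adjusted p = 2.98e-04, but adjusted p = 0.0630 with an estimated correlation). Epithelial markers had 14 of 16 members higher and 1 lower (median 1.07, adjusted p = 6.12e-06), including the mucin MUC1 (7.59±0.13) and the tight-junction proteins CLDN4 (2.25±0.11) and OCLN (1.45±0.07). Aldehyde dehydrogenases had 15 of 19 members higher and 3 lower (median 1.47, adjusted p = 0.00626), with ALDH1A1 at 5.24±0.77, adjusted p = 1.18e-05. Lysosome and autophagy genes had 17 of 19 members higher (median 0.92, adjusted p = 6.54e-07). ER stress and ATF4 genes had 15 of 18 members higher and 2 lower (median 0.55, adjusted p = 0.0415, but adjusted p = 0.418 with an estimated correlation). Markers of endothelial cells, another cell type, had 5 of 6 members higher (median 2.38, adjusted p = 0.0242, but adjusted p = 0.0630 with an estimated correlation), with VWF (6.07±0.29) and a sum of 131 ± 2.75 CPM against 26.4 ± 0.867 in parental_DMSO.

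TMT1A had no reads in parental_DMSO and was at least 786-fold higher, and the death ligand TNFSF10 rose by 10.74±0.39. BCAS1 (8.88±0.27), VTCN1 (8.80±0.25), CLIC3 (8.72±0.50), MMP12 (8.36±0.76), IGFBP5 (8.33±0.16), CP (8.31±0.35) and DEPP1 (7.77±0.26) followed, as did ALPG (8.30±0.19), which shares reads with near-identical alkaline phosphatase genes. The telomerase subunit TERT fell by 8.08±0.28, and HSD3B1 (-7.90±0.10), CSF2 (-7.63±0.49), CCAT1 (-6.99±0.32), COL13A1 (-6.93±0.13), IL1A (-6.83±0.11), MFSD2A (-6.58±0.23), IL1B (-6.40±0.14), HAS3 (-6.30±0.22) and IGFN1 (-6.22±0.22) were the other large decreases. After 24 hours 6445 genes were higher and 5778 lower (14500 changed without both TSA a, and 4612 higher and 7220 lower in spike-in scaling), and 12 of 30 gene lists passed (12 without both TSA a).

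The L1 family stood at 0.06±0.04 (adjusted p = 0.276; 0.06 without both TSA a) after 24 hours, and at -0.20 in repeat scaling. L1PA2 rose by 0.44±0.15, adjusted p = 0.0382, while L1HS stood at 0.00±0.15, adjusted p = 0.992, L1PA3 at 0.00±0.13, adjusted p = 0.989 and L1PA4 at 0.05±0.13, adjusted p = 0.807. Endogenous retrovirus families rose, with ERVK at 0.66±0.05, ERV1 at 0.57±0.04 and ERVL at 0.41±0.03, and so did SVA (0.56±0.09). ERVL-MaLR (0.23±0.03) and L2 (0.15±0.04) rose when scaled to gene reads but turned to -0.04 and -0.12 in repeat scaling, and to -0.13 and -0.22 in spike-in scaling. The AluY list was 1 repeat list of 14 to pass, with 5 of 20 members lower (median -0.09, adjusted p = 0.00835, but adjusted p = 0.224 with an estimated correlation). The simple repeat (CAGCTC)n was at least 82.9-fold higher, and MER65B (5.04±0.62), (GCCCCA)n (4.82±0.49), (TCTATG)n (3.72±0.66) and LTR108a_Mam (3.30±0.54) followed; BC200 (-2.49±0.26), LTR10B (-2.37±0.42), (CTCTGT)n (-2.19±0.50), LTR43B (-2.13±0.43) and (TCTC)n (-2.10±0.16) fell most. In all 266 subfamilies were higher and 73 lower, and 614 changed without both TSA a. The split was 144 higher and 178 lower in repeat scaling and 127 higher and 160 lower in spike-in scaling. L1PA2 lost its call without any 1 library (0.41 to 0.47, adjusted p = 0.0681 to 0.117).

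Cells after 72 hours of carboplatin were compared with parental cells to see the response to a drug with another mode of action. The p53 target list passed as higher. Targets of the tumour suppressor p53 had 13 of 23 members higher and 3 lower (median 0.33, adjusted p = 0.00130), including CDKN1A (1.85±0.09), GDF15 (4.51±0.22), TP53INP1 (4.67±0.17) and SESN2 (1.66±0.08). Inflammatory genes rose with them. The NF-kB and inflammatory list had 14 of 18 members higher (15 higher adjusted over the list alone, median 1.5 or 1.35 with low counts at bound, adjusted p = 1.14e-07), with TNF (3.45±0.18), IL6 (2.75±0.15), ICAM1 (2.08±0.06) and CXCL8 (1.56±0.07). Interferon response genes had 16 of 25 members higher and 2 lower (18 higher and 2 lower adjusted over the list alone, median 1.32 or 1.06 with low counts at bound, adjusted p = 0.00132), including IFI6 (4.81±0.23), IRF7 (2.19±0.19) and OASL (1.93±0.09). Cholesterol synthesis genes had 18 of 18 members higher (median 0.65, adjusted p = 6.66e-11), including INSIG1 (1.85±0.05) and MSMO1 (1.71±0.06). Lysosome and autophagy genes had 12 of 19 members higher and 4 lower (12 higher and 5 lower adjusted over the list alone, median 0.47, adjusted p = 2.45e-06). Markers of blood cells, another cell type that makes inflammatory genes, summed to 70.1 ± 1.91 CPM against 31.5 ± 1.42 in parental_DMSO, mostly CD68 (1.13±0.07) and CD14 (4.68±0.59).

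DNA replication genes fell when scaled to gene reads, with 2 of 25 members higher and 20 lower (median -0.59, adjusted p = 6.74e-05), including MCM6 (-0.87±0.05) and POLA1 (-2.11±0.13), but their median was 0.06 in spike-in scaling. Mitosis genes had 11 of 25 members higher and 3 lower (median 0.28, adjusted p = 0.0457, but adjusted p = 0.345 with an estimated correlation), and MKI67 stood at 0.18±0.18, adjusted p = 0.406. ER stress and ATF4 genes had 12 of 18 members higher and 4 lower (median 0.68, adjusted p = 6.74e-05, but adjusted p = 0.0960 with an estimated correlation), including ATF3 (4.32±0.09) and CHAC1 (3.31±0.17). Antigen presentation genes had 9 of 14 members higher and 1 lower (median 0.64, adjusted p = 0.0457, but adjusted p = 0.250 with an estimated correlation). Histone genes expressed outside S phase, which are near-identical and share reads, had 8 of 14 members higher and 4 lower (median 1.09, adjusted p = 0.0162, but adjusted p = 0.376 with an estimated correlation). Endothelial markers had 3 of 6 members higher (median 1.52, adjusted p = 0.0457, but adjusted p = 0.114 with an estimated correlation), which did not pass without both TSA a (adjusted p = 0.0606). EGFR fell by 1.77±0.33, adjusted p = 2.03e-04, ALDH1A1 stood at 0.52±0.86, adjusted p = 0.624, and SETDB1 fell by 0.40±0.10, adjusted p = 0.00285, but turned to 0.25 in spike-in scaling.

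The largest increases were RND1 (5.59±0.14), NATD1 (5.50±0.14), TENT5C (5.44±0.16), HAP1 (4.75±0.17), TP53INP2 (4.28±0.10), CNGB1 (4.05±0.17), AQP3 (3.99±0.18) and STC1 (3.88±0.10), together with GDF15 and ATF3. The largest decreases were SLC8A1 (-5.00±0.21), PTPRG (-4.86±0.16), SORCS2 (-4.83±0.16), SEMA5A (-4.42±0.20), SHANK2 (-4.16±0.14), FARS2 (-4.14±0.21), SCFD2 (-4.10±0.12), HDAC4 (-4.06±0.16), SUPT3H (-4.04±0.14) and LTBP1 (-4.02±0.16), where HDAC4 encodes a histone deacetylase and LTBP1 a TGF-beta binding protein. After carboplatin 5329 genes were higher and 5047 lower (13327 changed without both TSA a, and 10788 higher and 1215 lower in spike-in scaling), and 11 of 30 gene lists passed (11 without both TSA a).

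Most repeat families were higher relative to gene reads after carboplatin. The L1 family rose by 0.33±0.04 (adjusted p = 7.63e-06; 0.33 without both TSA a), by 0.98 in spike-in scaling, but stood at -0.23 in repeat scaling. ERVK (0.81±0.05), ERV1 (0.79±0.04), SVA (0.74±0.09), ERVL (0.63±0.03) and centr (1.22±0.25) rose; Alu (0.37±0.05), L2 (0.49±0.04), MIR (0.46±0.05), ERVL-MaLR (0.47±0.03) and Satellite (0.39±0.09) rose as well but turned to -0.18, -0.07, -0.09, -0.08 and -0.17 in repeat scaling. L1PA2 (0.42±0.15, adjusted p = 0.0335) and L1PA4 (0.47±0.13, adjusted p = 0.00793) rose, to turn to -0.14 and -0.09 under that scaling; L1HS stood at 0.25±0.15, adjusted p = 0.193 and L1PA3 at 0.21±0.13, adjusted p = 0.188. The MER41 and LTR13 list had 9 of 10 members higher (10 higher adjusted over the list alone, median 1.05, adjusted p = 0.00585, but adjusted p = 0.0514 with an estimated correlation). LTR12 and HERV9 had 8 of 10 members higher (median 0.79, adjusted p = 0.00630, but adjusted p = 0.170 with an estimated correlation). SVA had 6 of 6 members higher (median 0.73, adjusted p = 0.0256, but adjusted p = 0.376 with an estimated correlation), where SVA did not pass without both TSA a (adjusted p = 0.0521). AluY subfamilies had 6 of 20 members higher and 2 lower (median 0.14, adjusted p = 0.0154, but adjusted p = 0.170 with an estimated correlation), and because the test sets a list against the other subfamilies its direction was lower while the median was above 0 (-0.42 in repeat scaling). By subfamily the largest increases were HERVK13-int (2.35±0.24), MER52-int (2.33±0.70), HERVP71A-int (2.24±0.30), D20S16 (2.13±0.57) and GSATII (2.07±0.31) and the largest decreases BC200 (-1.91±0.25), (CTCTGT)n (-1.89±0.50), ORSL-2a (-1.76±0.26), (CAC)n (-1.62±0.43) and LTR1B1 (-1.45±0.29). Subfamilies higher numbered 499 and lower 20, and 820 changed without both TSA a. The split was 61 higher and 116 lower in repeat scaling and 966 higher and 9 lower in spike-in scaling. The median of all subfamilies was 0.54 relative to gene reads and -0.01 relative to repeat reads. L1PA2 lost its call without any 1 library (0.37 to 0.45, adjusted p = 0.0563 to 0.119). MER52-int lost its call without parental_DMSO b or parental_DMSO c (2.19 to 2.21, adjusted p = 0.0507 to 0.0537).

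Parental cells with and without TSA were compared to see what brief inhibition of histone deacetylases does in cells that had no other drug. Cholesterol synthesis genes rose throughout the list, with 18 of 18 members higher (median 1.34, adjusted p = 4.94e-25), led by INSIG1 (3.26±0.05) and SQLE (1.31±0.04). Neuronal and neuroendocrine markers had 4 of 6 members higher and 1 lower (median 1.78, adjusted p = 0.0161, but adjusted p = 0.132 with an estimated correlation), with the enolase ENO2 (3.88±0.09), the tubulin TUBB3 (1.73±0.17) and the synaptic vesicle protein SYP (1.83±0.66) higher and CHGA (-2.48±0.76) lower. Interferon response genes had 15 of 25 members higher (median 1.18 or 0.73 with low counts at bound, adjusted p = 0.00234), including IFI6 (4.23±0.25) and IFIT1 (3.76±0.21). Targets of p53 had 14 of 23 members higher and 3 lower (14 higher and 4 lower adjusted over the list alone, median 0.37, adjusted p = 0.0312, but adjusted p = 0.0887 with an estimated correlation), including TP53INP1 (4.17±0.17) and BTG2 (2.73±0.17) higher and MDM2 (-0.94±0.05) lower. Lysosome and autophagy genes had 14 of 19 members higher and 3 lower (median 0.48, adjusted p = 4.25e-04, but adjusted p = 0.131 with an estimated correlation), including TFEB (2.70±0.16) and NEU1 (1.73±0.07). The heterochromatin list had 4 of 22 members higher and 16 lower (4 higher and 17 lower adjusted over the list alone, median -0.51, adjusted p = 0.0161, but adjusted p = 0.425 with an estimated correlation), including SETDB1 (-0.97±0.10, adjusted p = 4.44e-07) and the silencing factor TASOR (-0.97±0.09). DNA replication genes had 18 of 25 members lower (19 lower adjusted over the list alone, median -0.33, adjusted p = 9.07e-05), including CCNE2 (-1.69±0.09) and MCM2 (-0.68±0.05). EGFR changed by -1.96±0.33, adjusted p = 8.02e-05 and MKI67 by -0.47±0.18, adjusted p = 0.0352; CDKN1A stood at 0.02±0.09, adjusted p = 0.880 and ALDH1A1 at -1.32±1.00, adjusted p = 0.273. SYP lost its call without parental_DMSO a, b or c (1.67 to 1.92, adjusted p = 0.0577 to 0.0885). CHGA lost its call without parental_DMSO a (-2.0, adjusted p = 0.0617). MKI67 lost its call without parental_DMSO b or c or parental_TSA a or b (-0.48 to -0.22, adjusted p = 0.0666 to 0.0919).

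DACT3 (7.94±0.26) rose most, followed by ABCG1 (4.82±0.23), HPCAL4 (4.49±0.20), PGF (4.30±0.24), TJP3 (3.91±0.14) and EPHB3 (3.90±0.11), ENO2, NEURL1B (3.83±0.10) and ZNF204P (3.61±0.13) and TUBA1A (3.84±0.08), which shares reads with other alpha-tubulin genes. The largest decreases were HSD3B1 (-3.53±0.07), CCAT1 (-3.33±0.25), CYP1B1 (-2.84±0.07), ZNF469 (-2.82±0.16), CLCF1 (-2.69±0.27), ADAMTS9 (-2.68±0.11), IGFN1 (-2.52±0.17), INHBA (-2.51±0.21) and ZNF649 (-2.51±0.26) and RNA5-8SN5 (-5.33±2.02), a ribosomal RNA gene measured here in polyA-selected libraries. With TSA 5428 genes were higher and 4836 lower (12512 changed without both TSA a), and 7 of 30 gene lists passed (8 without both TSA a). RNA5-8SN5 lost its call without parental_DMSO b or parental_TSA a, b or c (-5.76 to -2.02, adjusted p = 0.0616 to 0.354).

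L1 RNA was lower with TSA in parental cells. The L1 family changed by -0.37±0.04 (adjusted p = 8.65e-06; -0.33 without both TSA a) but lost its call in spike-in scaling (-0.35, adjusted p = 0.289). L1HS changed by -0.91±0.15, adjusted p = 3.95e-04, from 55.8 ± 1.91 to 29.6 ± 9.56 CPM, L1PA2 by -0.85±0.15, adjusted p = 6.57e-04 and L1PA3 by -0.43±0.13, adjusted p = 0.0160; L1PA4 stood at -0.36±0.13, adjusted p = 0.0534. The youngest L1 list had 7 of 9 members lower (8 lower adjusted over the list alone, median -0.73, adjusted p = 6.45e-04, but adjusted p = 0.296 with an estimated correlation). Primate L1 had 14 of 27 members lower (16 lower adjusted over the list alone, median -0.48, adjusted p = 0.00103, but adjusted p = 0.296 with an estimated correlation). L1M had 3 of 88 members higher and 51 lower (3 higher and 54 lower adjusted over the list alone, median -0.40, adjusted p = 3.88e-08, but adjusted p = 0.0913 with an estimated correlation). Parental_TSA a had the lowest L1HS level of its group, 19.1 CPM against 31.9 and 37.8 in its mates. Other lists went the other way: HERVH and LTR7 had 4 of 6 members higher (median 0.84, adjusted p = 0.0180, but adjusted p = 0.215 with an estimated correlation). HERVH-int ran from 604 to 1009 CPM, and from 787 to 885 in parental_DMSO. LTR12 and HERV9 had 4 of 10 members higher (median 0.43, adjusted p = 3.23e-05, but adjusted p = 0.0913 with an estimated correlation). MER41 and LTR13 had 5 of 10 members higher and 1 lower (6 higher and 1 lower adjusted over the list alone, median 0.48, adjusted p = 0.0388, but adjusted p = 0.131 with an estimated correlation). HERVK and LTR5 had 5 of 19 members higher (median 0.11, adjusted p = 0.0388, but adjusted p = 0.131 with an estimated correlation). SVA had 3 of 6 members higher (median 0.34, adjusted p = 0.0180, but adjusted p = 0.296 with an estimated correlation). Of these, MER41 and LTR13, HERVK and LTR5 (median -0.01) and SVA did not pass without both TSA a (adjusted p = 0.116, 0.116 and 0.102). Among families ERV1 (0.26±0.04), SVA (0.35±0.09), ERVK (0.18±0.05) and ERVL (0.09±0.03) rose, and Satellite (-0.33±0.09), MIR (-0.26±0.05) and L2 (-0.20±0.04) fell. Among subfamilies LTR54B (3.67±0.81), LTR2C (2.23±0.21), MER65-int (1.98±0.47), MLT1E2-int (1.91±0.56) and MER9a1 (1.91±0.31) rose most and (GATG)n (-2.82±0.29), (CTCTGT)n (-2.71±0.51), (TTTC)n (-2.60±0.36), L1P4 (-1.97±0.27) and LTR1B1 (-1.95±0.30) fell most. The test called 116 subfamilies higher and 202 lower (143 and 164 in repeat scaling), and 501 changed without both TSA a. L1PA3 (-0.41, adjusted p = 0.0564) lost its call without parental_DMSO b and SVA (0.25, adjusted p = 0.0512) without parental_TSA a. ERVL lost its call without parental_DMSO a or c or parental_TSA a or c (0.05 to 0.08, adjusted p = 0.0777 to 0.257). MLT1E2-int lost its call without parental_DMSO b or c or parental_TSA a (1.66 to 1.88, adjusted p = 0.0547 to 0.0640). L1PA4 passed without parental_TSA c (-0.53, adjusted p = 0.00387).

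**Figure D3:**
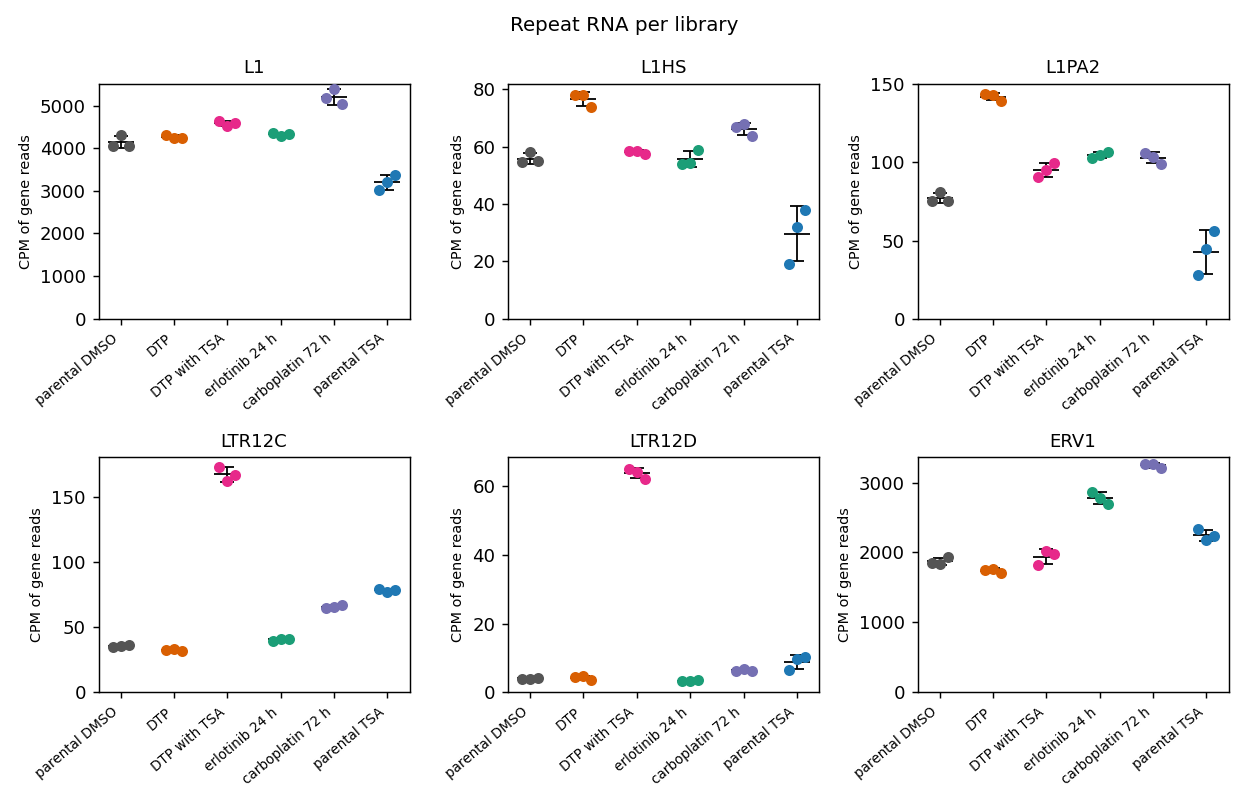
CPM of gene reads (vertical axis) of the L1 and ERV1 families and of the L1HS, L1PA2, LTR12C and LTR12D subfamilies in the 6 groups (horizontal axis), with 1 point per library and bars at the mean ± SD. L1HS is lower in parental_TSA than in parental_DMSO (-0.91), LTR12D is higher in DTP_TSA than in DTP (3.90), and the higher L1 of carboplatin_72h (0.33) turns to -0.23 in repeat scaling, as ERV1 in DTP_TSA (0.16) turns to -0.07.

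DTP cells with and without TSA were compared to see what histone deacetylase inhibition does in the drug-tolerant population. The interferon response genes that marked DTP fell, with 1 of 25 members higher and 22 lower (median -1.51, adjusted p = 5.49e-10), including IFIT3 (-2.86±0.17), IFIT2 (-2.54±0.11) and OAS1 (-1.12±0.07). DNA replication genes fell, with 23 of 25 members lower (median -0.55, adjusted p = 3.92e-06), including UHRF1 (-1.93±0.11) and RRM2 (-1.12±0.05). Mitosis genes had 1 of 25 members higher and 15 lower (median -0.53, adjusted p = 0.00161, but adjusted p = 0.173 with an estimated correlation), including PLK1 (-1.37±0.06) and CCNA2 (-1.12±0.05). The heterochromatin list had 4 of 22 members higher and 15 lower (4 higher and 16 lower adjusted over the list alone, median -0.55, adjusted p = 0.0137, but adjusted p = 0.376 with an estimated correlation), including SETDB1 (-1.53±0.10, adjusted p = 2.74e-09), DNMT3A (-1.34±0.09) and DAXX (-0.60±0.04). Factors that restrict L1 had 1 of 17 members higher and 11 lower (median -0.45, adjusted p = 0.0409, but adjusted p = 0.154 with an estimated correlation), including MOV10 (-0.72±0.07). The p53 target list had 12 of 23 members higher and 3 lower (13 higher and 3 lower adjusted over the list alone, median 0.32, adjusted p = 0.00818), including CDKN1A (1.15±0.09), BTG2 (2.31±0.16) and SESN2 (1.36±0.08). Its median was -0.01 in spike-in scaling of all libraries. MKI67 changed by -1.10±0.18, adjusted p = 7.04e-05, while EGFR stood at -0.61±0.32, adjusted p = 0.120 and ALDH1A1 at 0.99±1.14, adjusted p = 0.479.

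Neuronal and neuroendocrine markers had 3 of 6 members higher and 1 lower (4 higher and 1 lower adjusted over the list alone, median 1.26, adjusted p = 0.0243, but adjusted p = 0.154 with an estimated correlation). ENO2 rose (3.43±0.09), SNAP25, which had no reads in DTP, was at least 36.0-fold higher, and CHGA fell (-3.14±0.65). Histone genes expressed outside S phase had 8 of 14 members higher and 2 lower (median 0.44, adjusted p = 0.0137, but adjusted p = 0.489 with an estimated correlation), with a median of -0.05 in spike-in scaling of all libraries. Epithelial markers had 1 of 16 members higher and 10 lower (median -0.43, adjusted p = 0.0409, but adjusted p = 0.360 with an estimated correlation), including the splicing regulators ESRP1 (-0.77±0.05) and ESRP2 (-0.77±0.06). ER stress and ATF4 genes had 2 of 18 members higher and 9 lower (median -0.26, adjusted p = 0.0137, but adjusted p = 0.360 with an estimated correlation), including SLC7A11 (-2.19±0.09) and XBP1 (-1.92±0.08). The largest increases were DACT3 (6.79±0.22), SLC2A4 (6.48±0.24), TPPP (5.71±0.18), SYT11 (5.67±0.26), HPCAL4 (5.66±0.20), MAP1A (5.36±0.32), VWA5B2 (5.26±0.22), EFR3B (5.18±0.23) and LIX1L (4.69±0.19). The largest decreases were CLCF1 (-4.71±0.33), ZBED10P (-3.55±0.14), FOSL1 (-3.26±0.16), XAF1 (-2.94±0.18), KLHDC7B (-2.89±0.20), GRAMD2A (-2.88±0.15) and CALHM2 (-2.85±0.25), IFIT3 and GTF2IRD2B (-2.98±0.44), which shares reads with its paralogs. With TSA in DTP 4497 genes were higher and 5406 lower (12655 changed without both TSA a, and 4459 higher and 2577 lower in spike-in scaling), and 10 of 30 gene lists passed (10 without both TSA a).

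The LTR12 and HERV9 retroviral repeats rose with TSA in DTP, with 8 of 10 members higher (9 higher adjusted over the list alone, median 2.41, adjusted p = 1.07e-35). LTR12 (4.09±0.15), LTR12D (3.90±0.15), HERV9NC-int (3.52±0.28) and HERV9-int (3.39±0.18) and LTR54 (2.58±0.14) were the largest increases. The L1 family stood at 0.10±0.04 (adjusted p = 0.0750; 0.09 without both TSA a), at -0.12 in repeat scaling and at -0.34 in spike-in scaling of all libraries. It passed at 0.16 with DESeq2 (adjusted p = 0.00112) and at 0.16 with its size factors in edgeR (adjusted p = 0.0193). L1PA2 fell (-0.58±0.15, adjusted p = 0.0180), L1HS stood at -0.40±0.15, adjusted p = 0.0847, L1PA3 at -0.01±0.13, adjusted p = 0.973 and L1PA4 at 0.23±0.13, adjusted p = 0.243. The MER41 and LTR13 list had 6 of 10 members higher (median 0.44, adjusted p = 0.00521) but a median of -0.03 in spike-in scaling of all libraries. HERVH and LTR7 had 1 of 6 members lower (median -0.42, adjusted p = 0.0321, but adjusted p = 0.384 with an estimated correlation). ERVL (0.23±0.03), ERVK (0.19±0.05), ERV1 (0.16±0.04) and L2 (0.14±0.04) rose. In spike-in scaling of all libraries they were at -0.22, -0.29, -0.24 and -0.31, but kept their sign without DTP_TSA a. ERVK, ERV1 and L2 were at -0.04, -0.07 and -0.09 in repeat scaling. The largest decreases were (GCCCCA)n (-2.58±0.43), LTR1B1 (-1.59±0.31), ORSL-2a (-1.52±0.26), LTR2752 (-1.26±0.15) and LTR6B (-1.10±0.30). With TSA 134 subfamilies were higher and 44 lower, and 376 changed without both TSA a, 91 without DTP a, 93 without DTP b, 70 without DTP c. The split was 50 higher and 104 lower in repeat scaling and 56 higher and 7 lower in spike-in scaling. L1PA2 lost its call without DTP a, DTP b or DTP c (-0.60 to -0.58, adjusted p = 0.0509 to 0.0561). ERVK lost its call without DTP c (0.17, adjusted p = 0.0634). ERV1 lost its call without DTP a, DTP c or DTP_TSA c (0.13 to 0.15, adjusted p = 0.05004 to 0.0832). L2 lost its call without DTP a, DTP b, DTP c or DTP_TSA a (0.11 to 0.14, adjusted p = 0.0531 to 0.119). LTR6B lost its call without DTP a or DTP c (-1.12 to -1.06, adjusted p = 0.0542 to 0.0645).

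DTP cells were set against 24 hours of erlotinib to separate what is particular to prolonged survival from the early drug response. Interferon response genes were higher in DTP, with 25 of 25 members higher (median 4.62, adjusted p = 1.15e-67), including BST2 (5.99±0.13), IFI6 (5.79±0.13) and OAS1 (4.57±0.08). DNA replication genes were also higher than at 24 hours, with 24 of 25 members higher (median 1.87, adjusted p = 7.21e-39), including CDC6 (3.28±0.07) and RRM2 (2.75±0.06). EGFR-ERK output genes had 17 of 22 members higher and 3 lower (18 higher and 3 lower adjusted over the list alone, median 1.86, adjusted p = 4.04e-12), including ETV5 (4.91±0.14), HBEGF (3.18±0.07) and DUSP6 (2.58±0.09). Mesenchymal markers had 9 of 14 members higher and 1 lower (median 1.71, adjusted p = 3.55e-06), including FN1 (4.26±0.18) and TAGLN (4.21±0.10), where fibroblast markers summed to 65.4 ± 2.37 CPM in DTP and 38.6 ± 1.39 in erlotinib_24h. Cholesterol synthesis genes were lower, with 18 of 18 members lower (median -1.03, adjusted p = 4.41e-17). So were epithelial markers, with 2 of 16 members higher and 13 lower (median -0.86, adjusted p = 3.68e-07), including MUC1 (-3.45±0.11) and KRT8 (-1.53±0.08). Aldehyde dehydrogenases had 5 of 19 members higher and 11 lower (median -0.60, adjusted p = 0.0106), with ALDH1A1 at -6.86±0.88, adjusted p = 4.28e-06. CDKN1A rose by 2.77±0.10, adjusted p = 4.87e-13; MKI67 stood at -0.24±0.18, adjusted p = 0.278, EGFR at 0.30±0.32, adjusted p = 0.458, and SETDB1 fell by 0.44±0.10, adjusted p = 0.00128, but turned to 0.01 in spike-in scaling.

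Mitosis genes had 2 of 25 members higher and 14 lower (median -0.40, adjusted p = 0.0449, but adjusted p = 0.450 with an estimated correlation). Glycolysis and hypoxia genes had 2 of 16 members higher and 10 lower (median -0.33, adjusted p = 0.00193, but adjusted p = 0.199 with an estimated correlation), but the medians turned to 0.05 and 0.13 in spike-in scaling. The hypoxia-induced carbonic anhydrase CA9 had no reads in DTP and was at least 128-fold lower than at 24 hours. Ribosomal protein genes had 37 of 38 members lower (median -0.55, adjusted p = 1.95e-04, but adjusted p = 0.709 with an estimated correlation). The largest increases were OAS2 (10.30±0.23), IFI27 (9.05±0.31), XAF1 (8.91±0.26), IFI44L (8.63±0.32), IFI44 (6.46±0.17), SERPINB2 (6.25±0.11), HSD3B1 (6.22±0.10) and MX2 (5.92±0.28), BST2 and IFI6. The stem cell factor SOX2 (-8.74±0.61) led the decreases, with INPP5D (-8.61±0.39), CP (-8.44±0.35), CEACAM5 (-6.74±0.17), AGR2 (-5.95±0.13), ALDH3B2 (-5.25±0.46) and CASP14 (-4.91±0.07) and with SERPINB3 (-6.76±0.39), SERPINB4 (-5.79±0.39) and KRT6B (-5.04±0.33), which share reads with their paralogs. Against 24 hours 5382 genes were higher and 4375 lower (12900 changed without both TSA a, and 8508 higher and 1996 lower in spike-in scaling), and 10 of 30 gene lists passed (11 without both TSA a).

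The L1 family stood at -0.02±0.04 (adjusted p = 0.730; -0.02 without both TSA a) between DTP and 24 hours, at 0.22 in repeat scaling and at 0.43 in spike-in scaling. L1HS (0.46±0.15, adjusted p = 0.0414) and L1PA2 (0.44±0.15, adjusted p = 0.0492) were higher in DTP, with L1PA3 at 0.26±0.13, adjusted p = 0.171 and L1PA4 at 0.30±0.13, adjusted p = 0.136. The youngest L1 list had 4 of 9 members higher and 1 lower (6 higher and 1 lower adjusted over the list alone, median 0.30, adjusted p = 0.00979, but adjusted p = 0.580 with an estimated correlation). LTR12 and HERV9 had 2 of 10 members higher and 1 lower (4 higher and 1 lower adjusted over the list alone, median 0.20, adjusted p = 0.0209, but adjusted p = 0.399 with an estimated correlation). Without both TSA a 4 repeat lists passed. ERV1 (-0.68±0.04) and ERVK (-0.51±0.05) were lower. Alu (-0.23±0.05), MIR (-0.22±0.05) and ERVL-MaLR (-0.17±0.03) were lower too but turned to 0.02, 0.02 and 0.07 in repeat scaling. ERVL (-0.32±0.03), L2 (-0.26±0.04) and SVA (-0.40±0.09) kept their sign there but, in spike-in scaling, turned to 0.13, 0.19 and 0.05. Subfamilies furthest above 24 hours were MER57F (1.45±0.22), MLT1-int (1.43±0.36), HSAT4 (1.36±0.29), Charlie17 (1.33±0.14) and LTR7 (1.20±0.23), and furthest below were MER65B (-4.15±0.57), (TCTATG)n (-4.11±0.68), LTR40A1 (-2.50±0.31), LTR36 (-2.40±0.50) and MER65-int (-2.35±0.48). In DTP 47 subfamilies were higher and 187 lower, and 509 changed without both TSA a, 153 without DTP c. The split was 103 higher and 83 lower in repeat scaling and 122 higher and 38 lower in spike-in scaling. L1HS lost its call without any 1 library (0.45 to 0.50, adjusted p = 0.0717 to 0.121). L1PA2 lost its call without any 1 of these 6 libraries (0.44 to 0.46, adjusted p = 0.0956 to 0.131).

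The TSA effect in DTP was set against the TSA effect in parental cells by testing the difference between both, where a value above 0 means a higher response in DTP. The interferon response list went in opposite directions. The difference had 21 of 25 members lower (23 lower adjusted over the list alone, median -2.31, adjusted p = 5.19e-23), including IFIT1 (-5.55±0.24), IFI6 (-4.57±0.27) and OAS1 (-2.54±0.12). Cholesterol synthesis genes, which rose with TSA in parental cells, had 18 of 18 members lower (median -1.27, adjusted p = 9.38e-35), including INSIG1 (-3.16±0.07) and MSMO1 (-1.84±0.08). Mitosis genes had 18 of 25 members lower (22 lower adjusted over the list alone, median -0.77, adjusted p = 1.25e-10), including CCNB2 (-1.66±0.11) and PLK1 (-1.16±0.09). Factors that restrict L1 had 10 of 17 members lower (11 lower adjusted over the list alone, median -0.55, adjusted p = 0.00112), including APOBEC3F (-1.77±0.09) and MOV10 (-0.75±0.10). ER stress and ATF4 genes had 11 of 18 members lower (median -0.64, adjusted p = 2.72e-06, but adjusted p = 0.0648 with an estimated correlation). Lysosome and autophagy genes had 3 of 19 members higher and 11 lower (4 higher and 13 lower adjusted over the list alone, median -0.31, adjusted p = 0.00181, but adjusted p = 0.158 with an estimated correlation). Epithelial markers had 7 of 16 members lower (1 higher and 8 lower adjusted over the list alone, median -0.34, adjusted p = 0.00520, but adjusted p = 0.158 with an estimated correlation). Ribosomal protein genes had 37 of 38 members lower (median -0.59, adjusted p = 2.52e-04, but adjusted p = 0.728 with an estimated correlation). CDKN1A stood at 1.14±0.13, adjusted p = 3.73e-06, EGFR at 1.36±0.46, adjusted p = 0.0266, SETDB1 at -0.55±0.14, adjusted p = 0.00644, MKI67 at -0.63±0.25, adjusted p = 0.0600 and ALDH1A1 at 2.30±1.51, adjusted p = 0.249. EGFR lost its call without DTP a, DTP c, parental_DMSO b, parental_DMSO c or parental_TSA b (1.32 to 1.34, adjusted p = 0.0510 to 0.0567). MKI67 passed without parental_TSA a (-0.89, adjusted p = 1.12e-04).

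The genes with the smallest p and a higher response in DTP were SERPINB2 (4.57±0.16), ODC1 (2.37±0.08), POLR3G (1.73±0.09), HMGA2 (1.63±0.06) and RHPN2 (1.44±0.07). Those with a lower response were BHLHE40 (-3.64±0.09), INSIG1 (-3.16±0.07), CDKN2B (-2.95±0.09) and ICAM1 (-2.47±0.08) and TUBA1A (-3.87±0.10), which shares reads with other alpha-tubulin genes. By the test of the difference 2702 genes were higher and 4056 lower (9351 changed without both TSA a, and 1080 higher and 1621 lower in spike-in scaling), and 8 of 30 gene lists passed (9 without both TSA a). The L1 family differed by 0.48±0.06 (adjusted p = 5.52e-05; 0.42 without both TSA a), but lost its call in spike-in scaling (0.59, adjusted p = 0.407) and stood at 0.01 in that of all libraries. Among L1 subfamilies L1PA4 differed by 0.59±0.19, adjusted p = 0.0340; L1HS stood at 0.51±0.22, adjusted p = 0.0966, L1PA3 at 0.42±0.18, adjusted p = 0.0984 and L1PA2 at 0.27±0.22, adjusted p = 0.415. L1M subfamilies had 54 of 88 members higher and 1 lower (60 higher and 2 lower adjusted over the list alone, median 0.52, adjusted p = 8.25e-10). Primate L1 had 10 of 27 members higher (14 higher adjusted over the list alone, median 0.56, adjusted p = 0.00558, but adjusted p = 0.657 with an estimated correlation). The youngest L1 had 5 of 9 members higher (7 higher adjusted over the list alone, median 0.51, adjusted p = 0.0276, but adjusted p = 0.726 with an estimated correlation), where the median of the youngest turned to -0.01 in spike-in scaling of all libraries. The primate and youngest lists did not pass without both TSA a (adjusted p = 0.0632). L1PA4 lost its call without DTP a, b or c, DTP_TSA b or c or parental_DMSO a, b or c (0.54 to 0.61, adjusted p = 0.0541 to 0.0883). L1HS passed without parental_TSA a or parental_TSA c (0.28 to 0.72, adjusted p = 0.00856 to 0.0396). L1PA3 passed without parental_TSA c (0.58, adjusted p = 0.0115). L1PA2 passed without parental_TSA c (0.50, adjusted p = 0.0366).

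LTR12 and HERV9 repeats responded more in DTP, with 8 of 10 members higher (median 1.80, adjusted p = 1.37e-14), with LTR12 (2.79±0.19), LTR12D (2.78±0.20) and LTR12C (1.23±0.07), and HERVH and LTR7 less, with 4 of 6 members lower (median -1.22, adjusted p = 6.02e-05). LTR2C (-2.71±0.29), LTR18B (-1.64±0.21) and MER65C (-0.98±0.09) had the smallest p among lower responses. Of the families L2 differed by 0.34±0.05 (but -0.12 in spike-in scaling of all libraries), MIR by 0.31±0.07 (-0.19 in that scaling and -0.00 scaled to repeat reads) and ERVL by 0.14±0.04 (-0.31 and -0.17). The difference was above 0 for 185 subfamilies and below for 54, and 350 changed without both TSA a, 154 without DTP b, 157 without DTP c, 153 without parental_DMSO b. The split was 59 higher and 109 lower in repeat scaling and 38 higher and 17 lower in spike-in scaling. ERVL lost its call without DTP b, DTP c, DTP_TSA a, parental_DMSO b, parental_DMSO c or parental_TSA b (0.11 to 0.14, adjusted p = 0.0552 to 0.0984).

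Of the 30 gene lists, 10 passed camera in none of the 7 comparisons: the BCL2 family, receptor tyrosine kinases and adaptors, histone deacetylases, histone demethylases, germline antigens, mitochondrially encoded genes, and markers of fibroblasts, blood cells and alveolar type 1 and type 2 cells. Each passed in at most 1 comparison at an unadjusted p under 0.05, while fry, which tests whether the genes of a list move on balance one way, passed them in 1 to 7 comparisons. Markers of alveolar type 2 cells summed to 198 ± 2.30, 150 ± 3.45, 96.6 ± 1.70, 114 ± 4.30, 263 ± 12.6 and 205 ± 8.98 CPM, and markers of alveolar type 1 cells to 684 ± 9.96, 645 ± 6.30, 804 ± 12.2, 368 ± 7.69, 553 ± 40.3 and 398 ± 9.85 CPM, in the order parental_DMSO, DTP, erlotinib_24h, carboplatin_72h, parental_TSA and DTP_TSA.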

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

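The test of a swapped label for DTP_TSA a and the test of mixed RNA for parental_TSA a were chosen after their results were seen; the other tests were fixed before. The difference between the TSA effect in DTP and the TSA effect in parental cells was itself tested, and it singled out the results of this paragraph and the next. The interferon response list, higher with TSA in parental cells and lower in DTP, and the LTR12 repeats, which rose more in DTP, stood out. By this test 6758 genes, 239 repeat subfamilies, 8 gene lists and 5 repeat lists differed. Among 60 splits of the 12 libraries only the real split had as many genes (highest other 4686) or subfamilies (highest other 129). The L1 family difference of 0.48 was reached in 2 splits, the real one included (highest other 0.49). As many gene lists were found in 23 splits (highest other 12) and as many repeat lists in 6 (highest other 6). The splits mix real group differences into their groups, so these shares cannot tell whether chance gave the values.

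In log2 terms the TSA effect was higher in DTP for SERPINB2 (4.57), ODC1 (2.37), POLR3G (1.73), HMGA2 (1.63), RHPN2 (1.44), EGFR (1.36) and the cyclin kinase inhibitor CDKN1A (1.14). It was lower in DTP for TUBA1A (-3.87), BHLHE40 (-3.64), INSIG1 (-3.16), CDKN2B (-2.95), ICAM1 (-2.47) and SETDB1 (-0.55). Among repeats it was higher for LTR12 (2.79), LTR12D (2.78), LTR12C (1.23), L1PA4 (0.59) and the families L2 (0.34), MIR (0.31) and ERVL (0.14), and lower for LTR2C (-2.71), LTR18B (-1.64) and MER65C (-0.98). EGFR, L1PA4 and ERVL lost their calls when single libraries were left out (adjusted p up to 0.0567, adjusted p up to 0.0883 and adjusted p up to 0.0984). L2, MIR and ERVL turned to -0.12, -0.19 and -0.31 in spike-in scaling of all libraries, but kept their sign without DTP_TSA a.

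DTP_TSA a stood apart from its group, with nearly as many spike-in reads as gene reads. Lower depth is argued against, since the other pair of libraries, thinned to its gene reads, still correlated at 0.998. RNA of another group under this label is argued against, since the highest correlation of DTP_TSA a with its own group exceeded that with any other group by 0.0333. Transcript length does not account for its deviation, with a rho across genes of -0.0185. A GC bias stays open, with a rho of 0.161 that lies between both bounds set in advance and medians of -0.13 and 0.16 in the 10% of genes with the lowest and highest GC; genes are not independent replicates. Less cellular RNA in this sample may be the source of the spike-in share, but the design holds no group that tests a biological explanation.

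Parental_TSA a had lower L1HS than its mates (19.1 CPM against 31.8 and 37.8 after thinning). Thinning keeps mean CPM and argues only against counting error (lower level 39.9 SD of the draws above). Untreated RNA mixed into parental_TSA c is argued against: genes that TSA raised at least 4-fold in DTP covered 1.02 of the distance from parental_DMSO seen in parental_TSA a, against 0.490 for L1HS, a difference of 0.525. A first criterion, that genes raised and genes lowered cover like shares (1.02 and 0.974), was met and was replaced once that was seen, because shares near 1 leave no room for untreated RNA. Length and GC bias stay open, with rho across genes of -0.199 and 0.295, where the 10% of genes with the lowest and highest GC deviated less (-0.19 and 0.20) than L1HS (-0.85), and a real difference between cultures was not tested.

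For the pairwise comparisons the 10 splits of 6 libraries are too few for a share under 0.05. In the order DTP, erlotinib, carboplatin, TSA, TSA in DTP and DTP against 24 hours, 10377, 12223, 10376, 10264, 9903 and 9757 genes changed and 152, 339, 519, 318, 178 and 234 subfamilies. Other splits had 0 by edgeR, but each mixes both groups, so the splits cannot test the grouping. The L1 family stood at 0.04, 0.06, 0.33, -0.37, 0.10 and -0.02 with highest other values of 0.06, 0.07, 0.18, 0.19, 0.06 and 0.03 (4, 2, 1, 1, 1 and 2 splits as large). Gene lists numbered 11, 12, 11, 7, 10 and 10 with highest others of 12, 15, 11, 11, 6 and 10 (3, 6, 2, 8, 1 and 5 splits), and repeat lists 3, 1, 4, 8, 3 and 2 with highest others of 6, 3, 2, 7, 2 and 5 (5, 7, 1, 1, 1 and 3 splits).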

How the results depend on the processing

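The results without replicate a of both TSA groups and the spike-in results without DTP_TSA a come from tests chosen after seeing the data; the others were chosen before. Values in a series stand in the order DTP, erlotinib at 24 hours, carboplatin, TSA, TSA in DTP, DTP against 24 hours and the difference in TSA effects. Where a result changed the cause was not tested, except where the text names it. Among named genes and repeats, calls kept their side and direction in 429 results with DESeq2, 434 results with its size factors in edgeR, 366 results with no filter on low counts, 357 results with the stricter filter, 439 results with the replicate letter as a block and 399 results with the groups compared alone, while 3, 4, 0, 0, 1 and 16 lost and 11, 5, 0, 2, 3 and 22 gained a call. With the letter as a block no count or L1 family value left its range, and 11, 12, 10, 7, 10, 10 and 9 gene lists passed. The letters do not pair libraries across groups, as same-letter correlations of residuals ran from -0.05 to 0.10, with 1 of 45 above 0.1. Spike-in shares kept their sign without the most abundant spike-in and with repeat reads in the denominator.

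Camera with an estimated correlation passed 8, 7, 6, 3, 3, 7 and 4 gene lists and 0, 0, 0, 0, 2, 0 and 3 repeat lists. At an unadjusted p under 0.05 the repeat list counts were 2, 1, 3, 4, 2, 1 and 3. Fry, which does not compare a list with other genes, passed 28, 27, 25, 24, 22, 27 and 19 gene lists. Without replicate a of both TSA groups 3, 1, 4, 5, 3, 4 and 3 repeat lists passed, 410, 614, 820, 501, 376, 509 and 350 subfamilies changed, and centr turned to -0.35 for TSA in DTP, as it did without DTP_TSA a alone (leaving out single libraries gave -0.35 to 0.46). With the groups compared alone 411, 589, 797, 229, 95, 562 and 87 subfamilies changed. DESeq2 called 283 subfamilies and the L1 family (0.16, adjusted p = 0.00112) for TSA in DTP, and its size factors in edgeR called that family too (0.16, adjusted p = 0.0193).

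With spike-ins of all libraries as library sizes, where DTP_TSA a widens the spread, 288, 416, 75, 23, 29, 90 and 0 genes and 1, 1, 1, 0, 1, 0 and 0 subfamilies changed by edgeR. Unadjusted counts beside the values of 0 were 196 genes for the difference in TSA effects and 11, 5 and 2 subfamilies for TSA, DTP against 24 hours and the difference in TSA effects. Fry under this scaling passed 1, 0, 0, 0, 0, 1 and 0 gene lists, and 3, 2, 1, 0, 2, 2 and 1 at an unadjusted p under 0.05. The L1 family lost its call after carboplatin (0.98, adjusted p = 0.439), with TSA (-0.35, adjusted p = 0.988) and in the difference in TSA effects (0.0105, adjusted p = 1.00). Signs turned for ERVL-MaLR (-0.13) and L2 (-0.22) at 24 hours. They turned for SETDB1 (0.25) after carboplatin. They turned for ERV1 (-0.24), ERVK (-0.29), ERVL (-0.22) and L2 (-0.31) for TSA in DTP. They turned for Alu (0.23), ERVL (0.13), ERVL-MaLR (0.28), L2 (0.19), MIR (0.24), SETDB1 (0.0108) and SVA (0.0514) in DTP against 24 hours. They turned for ERVL (-0.31), L2 (-0.12) and MIR (-0.19) in the difference in TSA effects. With spike-ins and without DTP_TSA a 2701 genes changed in the difference in TSA effects, and 975, 63 and 55 subfamilies after carboplatin, for TSA in DTP and in the difference in TSA effects. The L1 family then lost its call with TSA (-0.35, adjusted p = 0.289) and in the difference in TSA effects (0.59, adjusted p = 0.407). Signs turned again for ERVL-MaLR (-0.13) and L2 (-0.22) at 24 hours, SETDB1 (0.25) after carboplatin, Alu (0.23), ERVL (0.13), ERVL-MaLR (0.28), L2 (0.19), MIR (0.24), SETDB1 (0.0109) and SVA (0.0514) in DTP against 24 hours.

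With repeats scaled to repeat reads the L1 family turned to -0.20 at 24 hours, -0.23 after carboplatin, -0.12 for TSA in DTP and 0.22 in DTP against 24 hours, and 177 subfamilies changed after carboplatin. This scaling sets each repeat against the other repeats, so a shift they share is removed by its construction. Other signs turned for Alu (-0.25), ERVL-MaLR (-0.0354), L2 (-0.12) and MIR (-0.16) at 24 hours. They turned for Alu (-0.18), ERVL-MaLR (-0.0819), L1PA2 (-0.14), L1PA4 (-0.0850), L2 (-0.0698), MIR (-0.0950) and Satellite (-0.17) after carboplatin. They turned for Alu (-0.14), ERV1 (-0.0673), ERVK (-0.0369), ERVL-MaLR (-0.14), L2 (-0.0904) and MIR (-0.18) for TSA in DTP. They turned for Alu (0.0153), ERVL-MaLR (0.0683) and MIR (0.0235) in DTP against 24 hours. They turned for Alu (-0.21), ERVK (-0.31), ERVL (-0.17), ERVL-MaLR (-0.27) and MIR (-0.00464) in the difference in TSA effects.

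Leaving out 1 library at a time gave counts of changed genes from 9470 to 9564, 11484 to 11574, 9382 to 9644, 9166 to 10505, 8955 to 10708, 8740 to 8825 and 5755 to 7857. Changed subfamilies ran from 99 to 120, 253 to 268, 404 to 455, 239 to 385, 70 to 225, 153 to 172 and 153 to 314, L1 family values from 0.02 to 0.07, 0.04 to 0.09, 0.27 to 0.36, -0.42 to -0.34, 0.09 to 0.11, -0.03 to -0.01 and 0.43 to 0.51 and spike-in shares, without the difference in TSA effects, from 0.0192 to 0.0654, 0.43 to 0.49, -0.57 to -0.38, -0.0426 to 0.28, 0.0392 to 3.79 and -0.45 to -0.39. The lowest spike-in share with TSA is the value without parental_TSA a, whose sign turned. In simulated data with DTP and parental depths 200 genes and 100 subfamilies were changed. That is fewer than the real calls, to which the rates may not carry over. Among genes with over 50 reads the edgeR test recovered 16, 44, 78 and 96% of those changed by 25%, 1.5, 2 and 4 times. It recovered 0, 40, 64 and 100% of subfamilies, and called 0.0472% and 0.204% of those left unchanged. Small changes at this depth can be missed.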

Other observations

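The genes of the first paragraph below were chosen after their values were seen (2 of 6 sets looked at), as was the spike-in scaling of long genes; the other tests of long genes were fixed before their results, though the pattern itself was noticed in the data. Genes that sense foreign nucleic acid went both ways in DTP. The RNA sensor RIGI stood at 172±4.16 CPM in DTP and 10.3±0.699 in parental_DMSO (mean ± SD, n = 3), a log2 change of 4.06±0.14, IFIH1 changed by 3.83±0.10 and the adaptor STING1 by 3.64±0.10, while the DNA sensor CGAS (-0.37±0.11) and the adaptor MAVS (-0.64±0.12) fell. With TSA in DTP RIGI, IFIH1 and STING1 changed by -1.59±0.13, -0.87±0.09 and -0.89±0.09. Of interferon transcripts the libraries held few reads: IFNB1 had 41 reads over the DTP group, 6 in DTP_TSA, 1 in parental_DMSO and 0 in erlotinib_24h, and IFNL1 had 11 in DTP and 0 in parental_DMSO. IFNE had 90 in parental_DMSO, 57 in DTP (-0.78±0.47, adjusted p = 0.167) and 172 in carboplatin_72h (0.90±0.45, adjusted p = 0.101).

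TSA changed 2911 genes to higher and 3157 to lower levels in both parental and DTP cells, where 1387 and 1486 would be shared if the calls were independent. A further 914 genes went in opposite directions, 599 of them higher in parental cells and lower in DTP and 315 the reverse. The effects correlated across genes at a Pearson r of 0.594 and a Spearman rho of 0.559, and genes are not independent replicates. Of subfamilies 28 were higher and 26 lower in both (14.1 and 8.07 if independent), and 16 went in opposite directions.

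Genes with a long genomic span were lower after carboplatin relative to other genes. Of the 10% of genes with the longest span (median 248 kb) 1000 of 1619 fell and 134 rose when scaled to gene reads, with a median log2 change of -0.76, against 204 and 618 of 1619 and 0.44 in the 10% with the shortest (median 2.71 kb). In spike-in scaling without DTP_TSA a the longest had 535 lower and 344 higher of 1617 (median -0.12), the shortest 55 and 1192 of 1619 (median 1.08), and rho was -0.358. Spearman's rho with span across 16185 genes was -0.359, and -0.124 to 0.0605 in the other pairwise comparisons. The mature transcript length and GC content are argued against as the cause, since rho with span was -0.360 given the first and -0.309 given the second. Given both and mean expression it was -0.294, so that the span, or a property that goes with it, may be the source, a hypothesis found and tested on the same data. Spans and lengths came from GENCODE, found for 92.0% of genes tested, and the annotation the counts were made with may differ.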
